A study of Mus musculus with 10 samples.

How the data were processed

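Expression was measured in splenic B cells of C57BL/6 mice on Illumina MouseWG-6 beadchips, in 10 arrays on 2 slides. Per the labels, B cells were stimulated for 5 h with LPS at 10 µg/ml, PMA at 50 ng/ml and ionomycin at 500 ng/ml, and IL-10 secreting cells were separated by a secretion assay followed by flow sorting. The labels give 5 arrays of IL-10+ cells, 3 of IL-10- cells and 2 of total B cells. The stimulation is stated in a protocol shared by every sample, so whether total B cells were treated identically rests on that shared text. The intensity table held no IL-10- arrays at the other replicate numbers, and every array in that table was analysed. Nothing states that replicates came from separate mice, so p-values measure the spread between these samples, which may be technical.

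The deposited non-normalized table holds the mean bead intensity per probe on a linear scale, exported from GenomeStudio 1.9.0 with no normalization, per the file headers. The deposited table also holds the intensity SD between beads and the number of beads behind each probe. Its deposited detection column is a score that rises with signal, and 1 minus this score was used as the detection p. Whether a background had been subtracted is not given in the sources used here, and the lowest signal per array lay between 89.9 and 119.6. A second deposited table holds the authors' processed log2 values for 9679 probes, with array medians between 8.54 and 8.62, and the submitters' processing notes name lumi. Its filter and normalization are not given in the sources used here, and its probe identifiers could not be paired with those of the intensity table, so it served only for counts.

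Background was corrected and arrays were quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with background inferred from the detection p and an offset of 16. Probes with a detection p under 0.01 on at least 2 arrays were kept, which left 16496 of 45281 probes. The probe with the highest mean over all arrays stood for each gene, which gave 11184 genes. Of 30854 distinct names in the file, 16265 equalled a RefSeq symbol and 5706 were a synonym of a single gene of assembly GRCm38.p6. Names were kept as in the file for 117 ambiguous and 8766 unmatched entries. No genome build is named for the probes, so no coordinates are given.

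Groups were compared with lmFit and eBayes of limma in a single fit of all 10 arrays, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The residual degrees of freedom were 7, and 10.6 after moderation. A gene undetected on every array of a group was given an "at least" fold, from the bright group's mean against the lowest detected signal per array or the dim probe's own value, whichever was higher. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, where 5 or more members were measured. The fry test asks whether a list's genes move, on balance, in a single direction and does not compare them with other genes.

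The lists, the tests of the 3 comparisons and of the lists, and the rule for named genes were fixed before the data were examined, and tests chosen later are named with their results. The rule took Il10, the 15 largest rises and 15 largest falls between IL-10+ and IL-10- cells whose arrays did not overlap, the 8 largest rises and falls in each comparison with total B cells, and up to 4 passing members per list, or the 2 with the smallest p where none passed. Genes known only by a clone, LOC, Gm or Rik name were counted and not named. Of 121 genes named by the rule between IL-10+ and IL-10- cells, 38 had another detected probe, and for 5 a further probe had the opposite sign.

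The fit was tested on simulated data drawn from the real means and SDs of the 11184 genes. For IL-10+ against IL-10- cells it recovered 20% of genes changed by 0.5 log2, 76% of those changed by 1 and 100% of those changed by 2. For IL-10+ against total B cells the shares were 12%, 60% and 94%, and for IL-10- against total B cells 8%, 44% and 98%. Among the genes left unchanged, 15, 6 and 10 were falsely called in these comparisons, in the same order. Only 50 genes were changed by each size per comparison, with noise drawn independently for each gene. Slide, pairing and correlation between genes were not simulated, and many more genes passed in the real data. The shares therefore describe the simulated setting only.

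Same-numbered IL-10+ and IL-10- arrays deviated together from their group means, with correlations across genes of 0.347, 0.238 and 0.319 for replicates 2, 3 and 5, so the numbers were taken to pair the samples. Pairs also shared a slide, and IL-10+ replicate 4 and IL-10- replicate 5, on slide 2 with different numbers, had a correlation of 0.276. Differently numbered pairs on slide 1 had correlations of -0.023 to 0.064. The pairing comes from the numbers in the sample titles. Alternatives covered the background correction, scaling, probe filter, probe choice, slide, replicate block, array weights, the groups in the fit and the omission of each array. The replicate block between IL-10+ and IL-10- cells left out the total B arrays. IL-10+ replicates 1 and 4 have no IL-10- partner, so its changes rest on replicates 2, 3 and 5. Fewer residual degrees of freedom remain than in the main fit, so a call lost with this block may reflect that loss or the pairing.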

Results

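Gene expression was profiled in mouse splenic B cells sorted by secretion of IL-10, an anti-inflammatory cytokine, after stimulation with LPS, PMA and ionomycin. There were 5 IL-10+ arrays, 3 IL-10- arrays and 2 arrays of total B cells. Between 13910 and 15610 of 45281 probes were detected per array, and the number of arrays limits the precision of every value. IL-10+ arrays had 14990 ± 428 detected probes (SD, n = 5) and IL-10- arrays 14104 ± 202 (SD, n = 3). The difference of 885.9 gave an exact two-sided permutation p of 0.0179, the smallest that the 56 splits allow, and it was 961.5 within slide 1 and 821 within slide 2. Mean signal differed by 182 units, with an exact two-sided permutation p of 0.107, and by 209 and 100 units within the slides. Both tests ignore the replicate pairs, and in a test within pairs, chosen after seeing the data, both measures were higher in IL-10+ cells in 3 of 3 pairs, with an exact permutation p of 0.25, the smallest that 3 pairs allow. Correlations of log2 values across genes, which are not independent replicates, were 0.980 to 0.991 among IL-10+ arrays, 0.970 to 0.984 among IL-10- arrays and 0.946 to 0.971 between these groups.

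Il10, whose product set the sort, checked the sample labels. Its level was 13.18 ± 0.28 on the log2 scale in IL-10+ cells (SD, n = 5), 7.75 ± 0.19 in IL-10- cells (SD, n = 3) and 10.26 ± 0.53 in total B cells (SD, n = 2). The change between the sorted fractions was 5.44 ± 0.21 (SE), or 43.3-fold, with a limma adjusted p of 5.98e-07. Both total B arrays lay between the fractions.

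The comparison of IL-10+ with IL-10- cells asked how B cells that secrete the cytokine differ from those that do not. Genes associated with regulatory and B-1 B cells were higher in IL-10+ cells and follicular B cell genes lower, as lists tested with a preset correlation. They had adjusted p = 0.0798, 0.0592 and 0.0798 with an estimated correlation. Among the largest rises was that of the heavy chain variable gene IGH-V11, by 5.59 ± 0.33 log2 (SE, n = 5 and 3), or 48.1-fold, with an adjusted p of 1.27e-05. Another heavy chain variable gene, IGHV10S3, rose 16.3-fold. Mt1, a metallothionein, rose by 3.84 ± 0.38 (SE) and Cdkn2b, a cell cycle inhibitor, by 3.81 ± 0.27 (SE). Tubb6, a tubulin, rose 9.37-fold, Nt5e, the ectoenzyme CD73, 8.88-fold, the calcium-binding S100a6 8.46-fold and Rap1gap 8.30-fold. Oosp1 rose at least 6.02-fold and Ly6c1 at least 6.00-fold, both undetected on the IL-10- arrays. IGH-V11, IGHV10S3, Cdkn2b and Nt5e were detected on 2 of 3 IL-10- arrays and Rap1gap on 1 of 3. With IL-10- arrays raised to the lowest detected signal, a calculation chosen after seeing the data, the folds of IGH-V11 and Rap1gap were 39.7 and 6.45. Without IL-10- replicate 2 the change of Nt5e was 2.51 against 3.15 log2.

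Mmp13, a matrix metalloproteinase, fell by 2.57 ± 0.70 on the log2 scale (SE), and Fcer2a, the low-affinity IgE receptor CD23, was 5.81-fold lower. Klf2, a transcription factor of quiescent lymphocytes, was 4.55-fold lower, with a change of -1.57 log2 and an adjusted p of 0.166 without IL-10- replicate 2. Klf2 and Mmp13 each lost the threshold in 6 of 8 omissions of a single array, Mmp13 with an adjusted p of up to 0.0942, without IL-10- replicate 5. Zfp608 was 4.70-fold, Rgl1 4.61-fold, Sox4 3.81-fold and Gadd45g 3.49-fold lower. Epb41l4b was at least 4.27-fold lower, Sorl1 at least 3.45-fold and the heat shock gene Hspa1a at least 2.79-fold, each undetected on the IL-10+ arrays at the tested probe, although another probe of Epb41l4b was detected on 1 of 5. Rgl1 was detected on 3 of 5 IL-10+ arrays and Sox4 on 1 of 5, and the fold of Sox4 was 3.24 with these arrays raised in the same way.

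**Figure D1:**
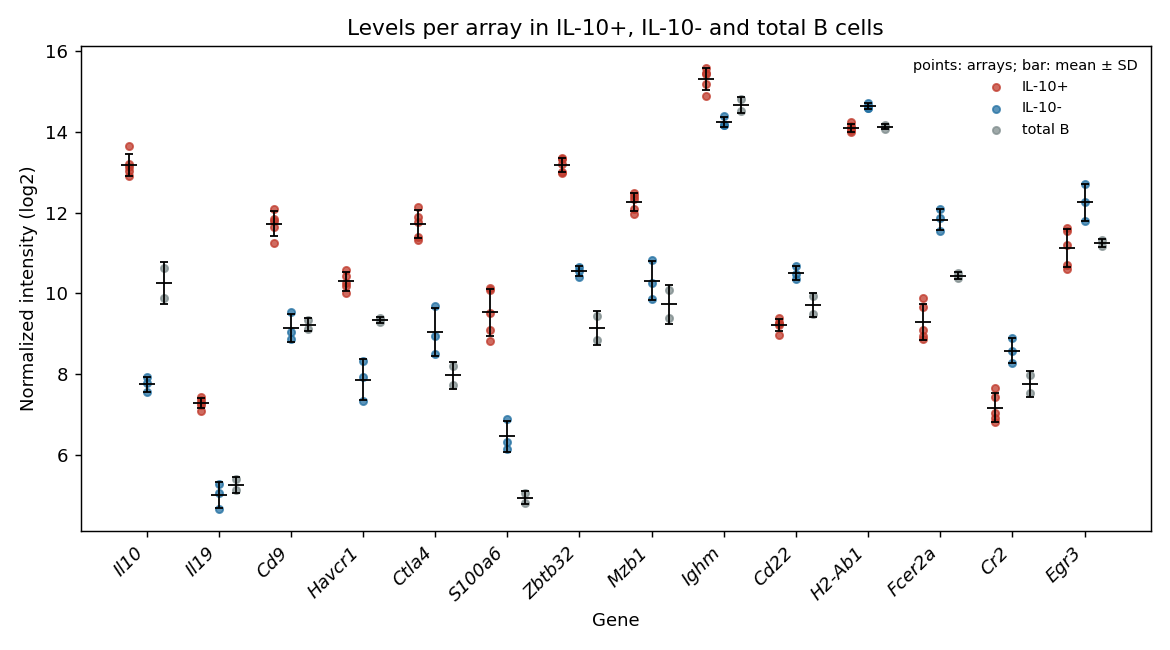
Normalized log2 intensity (vertical axis) of 14 named genes (horizontal axis) on every array, with points for arrays and black bars for mean ± SD of IL-10+ (n = 5), IL-10- (n = 3) and total B cells (n = 2). Il10 had means of 13.18, 7.75 and 10.26, and Fcer2a was higher in IL-10- cells, at 11.83 against 9.29 in IL-10+ cells.

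In all, 2028 of 11184 genes passed, 1020 higher and 1008 lower in IL-10+ cells, and 675 of these changed at least 2-fold. Clone-type names made up 462 of the passing genes. The arrays of the 2 groups did not overlap for 24.5% of all genes, against 3.57% by chance. Without IL-10- replicate 2 the count was 1255, with 697 higher and 558 lower. A replicate block between the fractions rests on 3 pairs, with fewer residual degrees of freedom than the main fit. With the replicate number as a block the count was 1337, with slide as a block 2400, within slide 1 751 and within slide 2, with a lone IL-10- array that is assumed to vary like the other groups, 617. Scaling arrays by their medians put the median of all genes at 0.48, against -0.03, and gave 2438 genes higher and 78 lower, so changes are given relative to the quantile-normalized median. These array medians were taken over all 45281 probes, of which 30.72% to 34.47% were detected per array. The scaling thus rests on undetected probes near background.

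Genes associated with regulatory B cells were higher as a list, with 8 of 15 measured members that rose, 1 that fell and 6 that did not pass. Cd9, a tetraspanin, rose 5.95-fold, Havcr1, the receptor TIM-1, 5.39-fold and Ctla4, an inhibitory receptor, 6.32-fold. Of 14 measured genes of B-1 cells, an innate-like B cell lineage, 10 rose and 1 fell, with Zbtb32 at 6.22-fold and Anxa2 at 6.31-fold higher. Of 13 plasmablast and plasma cell genes 9 rose and 1 fell, with Mzb1, an endoplasmic reticulum protein, at 3.87-fold higher. Prdm1, the regulator of plasma cell differentiation, rose at least 2.02-fold. Jchain, which joins IgM and IgA units, rose 5.57-fold, but with the replicate block its change of 1.98 log2 had an adjusted p of 0.0574. Of 6 immunoglobulin genes 5 rose, with the constant region Ighm at 2.08-fold and Iglv1 at 2.86-fold higher, and IGHG had an adjusted p of 0.0542 with the replicate block and did not pass in 7 of 8 omissions of a single array, with up to 0.154 without IL-10- replicate 2. Adjusted over the list alone, these 4 lists had 8, 11, 9 and 5 members higher and 2, 1, 2 and 0 lower. Their camera adjusted p values were 0.000517, 5.14e-09, 0.000137 and 0.000138, against adjusted p = 0.0798, 0.0592, 0.0592 and 0.295 with an estimated correlation. The lists share members, such as Cd9, Ctla4 and Jchain.

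Of 27 proliferation genes 9 rose and none fell, with Tyms at 2.96-fold, Cdc6 at 2.75-fold, Cdk1 at 2.55-fold and Mki67 at 2.34-fold higher. In IL-10+ against total B cells 6 of the 27 rose and 2 fell, and the list had a camera adjusted p of 0.331. Tyms and Cdc6 lay higher on every IL-10+ array than on both total B arrays, but Cdk1 and Mki67 did not. Of 26 endoplasmic reticulum stress and secretory genes 8 rose, with Asns at 3.43-fold, while Ddit3, a stress-induced transcription factor, was 2.71-fold lower. Of 8 measured neighbours of Il10 on its chromosome 3 rose. Il19, the adjacent gene, rose at least 2.94-fold and Pigr at least 1.31-fold, with an adjusted p of 0.0517 for Pigr with the replicate block. Il24, undetected on the IL-10- arrays, passed with an adjusted p of 0.0488. Its fold was 0.879 with these arrays raised to the lowest detected signal, so no rise above background was shown. Pigr and Il24 did not pass in 5 and 6 of 8 omissions of a single array, with adjusted p values of up to 0.1 without IL-10- replicate 3 and 0.146 without IL-10- replicate 5. Of 6 macrophage and monocyte markers Mpeg1 rose 2.98-fold, and Hmox1 and Spic, undetected on the IL-10- arrays, passed as well. With these arrays raised in the same way, the folds of Hmox1 and Spic were 0.918 and 0.873, so no rise above background was shown for them. Adjusted over the list alone, 10, 9, 4 and 3 members of these lists were higher, and 0, 1, 0 and 0 lower. Their camera adjusted p values were 3.54e-05, 0.00254, 0.00519 and 0.0468, against adjusted p = 0.356, 0.295, 0.0871 and 0.284 with an estimated correlation. The macrophage list did not pass in 9 of 17 alternatives, with an adjusted p of 0.063 with the replicate block, 0.0646 without background correction, 0.148 under median scaling, 0.0917 within slide 2 and up to 0.109 with single arrays left out, without IL-10- replicate 5. The Il10 neighbours had an adjusted p of 0.083 within slide 2.

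Lower in IL-10+ cells were follicular B cell genes, with 7 of 11 lower and Itgb7 higher. Of 18 B cell identity genes 4 fell, among them the complement receptor Cr2 at 2.65-fold and the inhibitory receptor Cd22 at 2.44-fold lower. Of 10 MHC class II genes 4 fell, among them Ciita, the transactivator of the class, by 0.93 ± 0.17 on the log2 scale (SE), and H2-Ab1, at 1.44-fold lower. Of 24 immediate early genes 8 fell, with Klf4 at 2.26-fold, Egr3 at 2.18-fold and Fosb at 2.09-fold lower. These 3 and Itgb7 did not pass in 2, 2, 5 and 6 of 8 omissions of a single array, with adjusted p values of up to 0.075, 0.0778, 0.139 and 0.15, each without IL-10- replicate 2. Of 24 NF-kB target genes 8 fell and 1 rose, with Bcl3 at 2.73-fold, Cflar at 2.06-fold and Icam1 at 1.69-fold lower. Adjusted over the list alone, 10, 4, 6, 10 and 10 members of these lists were lower, and 1, 0, 0, 0 and 2 higher. Their camera adjusted p values were 5.88e-05, 0.021, 0.00137, 0.00355 and 0.00355, against adjusted p = 0.0798, 0.356, 0.295, 0.371 and 0.332 with an estimated correlation. Under median scaling, the fitted medians of B cell identity, immediate early and NF-kB genes were 0.27, 0.08 and 0.19, above 0 yet below the median of all genes, 0.48. B cell identity genes had an adjusted p of 0.063 with the replicate block, 0.148 without IL-10- replicate 2 and 0.542 within slide 2, where MHC class II genes had 0.24 and NF-kB genes 0.439.

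**Figure D2:**
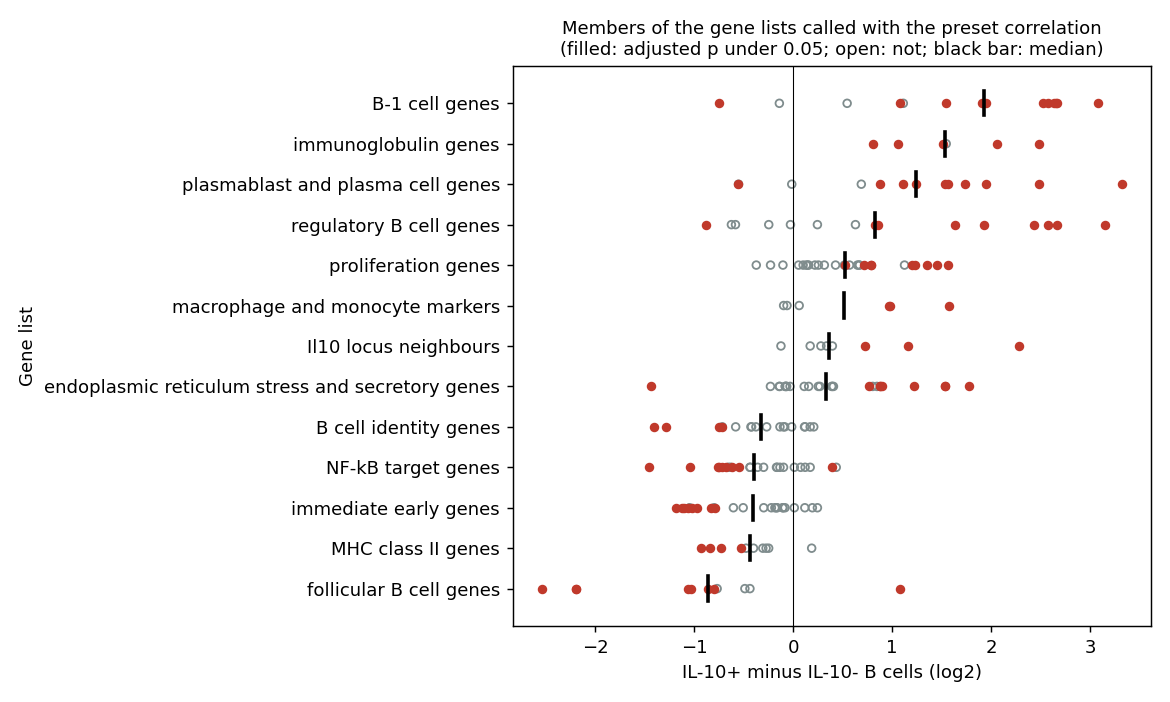
Change between IL-10+ and IL-10- cells in log2 (horizontal axis) of each measured member of the 13 gene lists (vertical axis) that passed camera with the preset correlation; filled points passed the adjusted p threshold of 0.05, open points did not, and black bars are fitted list medians. Fcer2a, at -2.54, was the lowest follicular gene, and under median scaling the medians of B cell identity, immediate early and NF-kB genes lay above 0.

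The other lists did not pass camera as a whole in the main fit, with adjusted p values from 0.0598 to 0.844, although members did. With slide as a block 15 lists passed, against 13 in the main fit. Of 25 cytokine and chemokine genes 9 rose and 3 fell, with Ccl5 at 5.48-fold, Cxcl10 at 3.13-fold and Il6 at least 2.71-fold higher. Of 21 costimulation and checkpoint genes 6 rose and 3 fell, with Cd70 at least 3.86-fold and Cd80 at least 3.28-fold higher, and their median was -0.22 while their mean was 0.39. Of 11 marginal zone genes 4 rose and 2 fell, with Fcrl5 at least 3.23-fold and Cd1d1 at least 2.28-fold higher. Cr2 and Gpr183 were the 2 that fell. The 4 that rose, Fcrl5, Cd1d1, Cd9 and Mzb1, are also members of the regulatory, B-1 or plasmablast lists. The marginal zone list's adjusted p of 0.0598 became 0.0331 with the replicate block, against adjusted p = 0.269 with an estimated correlation and no block. Of 23 interferon response genes 4 rose and 2 fell, with Ifih1, detected on 2 of 3 IL-10- arrays, at 7.35-fold and Rsad2 at 4.14-fold higher. Of 14 transcription factors tied to Il10 expression 2 rose and 5 fell, with Ets1 at 2.19-fold and Irf8 at 1.69-fold lower, and Irf8 did not pass in 3 of 8 omissions of a single array, with an adjusted p of up to 0.0605 without IL-10- replicate 2. Of 7 T cell markers Zap70, detected on 1 of 3 IL-10- arrays, and Cd2 rose and Il7r fell. Cd3g, undetected on the IL-10- arrays, passed as higher, but its fold was 0.99 with these arrays raised to the lowest detected signal. No rise of Cd3g above background was thus shown. Adjusted over the list alone, 10, 6, 5, 5, 2 and 3 members of these 6 lists were higher and 6, 4, 2, 2, 6 and 1 lower.

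Toll-like receptor, heat shock, apoptosis and migration lists had 3, 2, 1 and 1 members that rose and 2, 2, 3 and 4 that fell. Glycolysis, cholesterol synthesis, ribosome biogenesis and dendritic cell lists had 3, 1, 1 and 0 that rose and 0, 1, 3 and 1 that fell. Adjusted over the list alone, these 8 lists had 4, 2, 1, 2, 3, 3, 1 and 0 members higher and 4, 2, 3, 5, 0, 2, 3 and 1 lower. Bag3, a cochaperone, rose 4.28-fold, and Gpr183, a chemotactic receptor, was 2.83-fold lower. With the replicate block, Gpi1, Ppan and Rrp9 had adjusted p values of 0.125, 0.0983 and 0.0569, and Gpi1 and Ppan did not pass in 7 and 6 of 8 omissions of a single array, with up to 0.103 and 0.117 without IL-10- replicates 5 and 2. None of 23 ribosomal protein genes or 26 oxidative phosphorylation genes passed in limma, over all genes or over the list alone, and 1 and 2 had an unadjusted p under 0.05. Median and mean lay on opposite sides of 0 in these 2 lists, at 0.03 and -0.01 for the first and -0.02 and 0.03 for the second. Germinal centre, natural killer, basophil and erythroid lists had 4, 2, 1 and 4 measured members and were not tested as lists. In them Bcl6, a germinal centre regulator, was 2.05-fold and Hbb-b1, a globin, 2.31-fold lower, Ccl5 rose, and Hdc had an adjusted p of 0.903. No neutrophil marker was measured.

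The comparison of IL-10+ with total B cells set the secreting cells against the unsorted group. Zbtb32, a transcription factor of the B-1 list, rose by 4.03 ± 0.18 log2 (SE, n = 5 and 2), or 16.3-fold, with an adjusted p of 2.04e-06. S100a6 was at least 15.5-fold higher, IGH-V11 17.7-fold, the inhibitory receptor Lag3 14.8-fold, Cdkn2b 13.9-fold and Ctla4 13.4-fold. Lag3 and Cdkn2b were detected on 1 of 2 total B arrays, and with these raised to the lowest detected signal the fold of Lag3 was 10.5. The level of Lag3 was 9.475, 9.733 and 9.476 log2 on the IL-10+ arrays of slide 1. It was 8.231 and 8.185 on those of slide 2, where both total B arrays lay, so both folds exceed the difference on slide 2. Irs2, an insulin receptor substrate, fell by 3.01 ± 0.32 on the log2 scale (SE), Epb41l4b was at least 9.10-fold lower, Ifitm2 6.01-fold and Vegfa, an angiogenic factor, 5.99-fold lower, with a change for Vegfa of -1.89 log2 without total B replicate 1 and -3.27 without replicate 2. Irs2, Epb41l4b, Ifitm2 and Vegfa were also lower on every IL-10- array than on both total B arrays, with Irs2 at 11.133 to 12.04 against 13.198 and 12.784 log2. Zbtb32, S100a6, Lag3 and Ctla4, but not IGH-V11 and Cdkn2b, were likewise higher on every IL-10- array than on both. Genes past the threshold numbered 2501, with 1341 higher and 1160 lower. Camera passed 7 lists, all higher. Of 14 B-1 cell genes 12 rose, and of 23 interferon response genes, which antiviral signalling induces, 13 rose and none fell. Regulatory, plasmablast, immunoglobulin, Il10 neighbour and endoplasmic reticulum lists had 10 of 15, 6 of 13, 2 of 6, 3 of 8 and 7 of 26 members that rose and 1, 1, 0, 0 and 1 that fell. Adjusted over the list alone, these 7 lists had 12, 15, 11, 9, 4, 4 and 8 members higher. The B-1 list had an adjusted p = 0.0415 with an estimated correlation, and the others had adjusted p = 0.414, 0.0789, 0.183, 0.586, 0.0789 and 0.455 with an estimated correlation.

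All total B arrays lay on slide 2. The count for IL-10+ against total B cells was 2090 within slide 2 and 2427 with slide as a block. It was 1015 without total B replicate 1 and 1273 without replicate 2, each leaving a lone total B array that is assumed to vary like the other groups. Median scaling gave 1318 genes, 77.9% of them higher against 53.6%, with the median of all genes at 0.23 against -0.01, and the endoplasmic reticulum list then had an adjusted p of 0.0579. Without total B replicate 2 the plasmablast, immunoglobulin and endoplasmic reticulum lists had adjusted p values of 0.0745, 0.15 and 0.0506. The immunoglobulin list had 0.0582, 0.0531 and 0.0576 without IL-10+ replicates 1, 4 and 5, and 0.0714 with fry. With the replicate block, glycolysis genes and macrophage markers passed, at adjusted p values of 0.0254 and 0.0336, against adjusted p = 0.586 and 0.376 with an estimated correlation and no block. That block ties total B replicates 1 and 2 to IL-10+ replicates 1 and 2, which lay on the other slide. This pairing by number was not checked.

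The comparison of IL-10- with total B cells set the non-secreting cells against the unsorted group. Fosb, an immediate early transcription factor, rose by 3.42 ± 0.40 log2 (SE, n = 3 and 2), or 10.7-fold, with an adjusted p of 0.00112. The prion protein gene Prnp was 8.11-fold, Gbp2 7.84-fold and Atf3 7.27-fold higher. Fosb, Prnp, Gbp2 and Atf3 also lay higher on every IL-10+ array than on both total B arrays, so these rises were not particular to non-secreting cells. Prnp lay at 10.251 to 10.897 log2 on IL-10+ arrays, against 7.163 and 7.942 on total B arrays. Klf2 changed by 3.32 ± 0.83 log2 (SE), but by 4.60 without total B replicate 1, and by 2.05 with an adjusted p of 0.2 without total B replicate 2 and 2.71 with 0.0609 without IL-10- replicate 2. Gbp2 had an adjusted p of 0.0622 without total B replicate 1. Il10 was 5.71-fold lower than in total B cells, IGHV10S3, detected on 2 of 3 IL-10- arrays, 6.54-fold and RN18S, the 18S ribosomal RNA, 5.56-fold lower. The change of RN18S was -2.48 log2, and -1.82 without IL-10- replicate 5. Without total B replicates 1 and 2 in turn, RN18S had adjusted p values of 0.0627 and 0.0738, and IGHV10S3 0.0625 and 0.0782. Genes past the threshold numbered 1519, with 842 higher and 677 lower. Camera passed 5 lists. Higher were 6 of 23 interferon response genes, 5 of 11 follicular, 4 of 18 B cell identity and 3 of 14 B-1 cell genes, with 0, 0, 0 and 1 lower, and 7 of 27 proliferation genes were lower with none higher. The first 4 lists had 12, 6, 5 and 6 members higher adjusted over the list alone, and the proliferation list 9 lower. Each of the 5 lists had an adjusted p = 0.743 with an estimated correlation.

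Within slide 2, with a lone IL-10- array, 1215 genes passed between IL-10- and total B cells, and with slide as a block 1200. Of these 5 lists only interferon response genes passed within slide 2, at an adjusted p of 0.00193. The B cell identity, B-1, follicular and proliferation lists did not pass in 7, 5, 5 and 9 of 11 alternatives, and the interferon list in 1, the estimated correlation. Without IL-10- replicate 2 those 4 had adjusted p values of 0.261, 0.069, 0.07 and 0.198, and without total B replicate 2 the first 3 had 0.198, 0.198 and 0.0739. Without IL-10- replicate 3 the B cell identity and proliferation lists had 0.0796 each, and without total B replicate 1 the proliferation list had 0.0594. The gene count was 398 without total B replicate 1, 506 without replicate 2 and 431 in a fit of the 2 groups alone. Median scaling gave 606 genes, 16.8% of them higher against 55.4%, with the median of all genes at -0.27 against 0.01, a fitted median of -0.001 for B cell identity genes and an adjusted p of 0.0526 for proliferation genes.

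**Figure D3:**
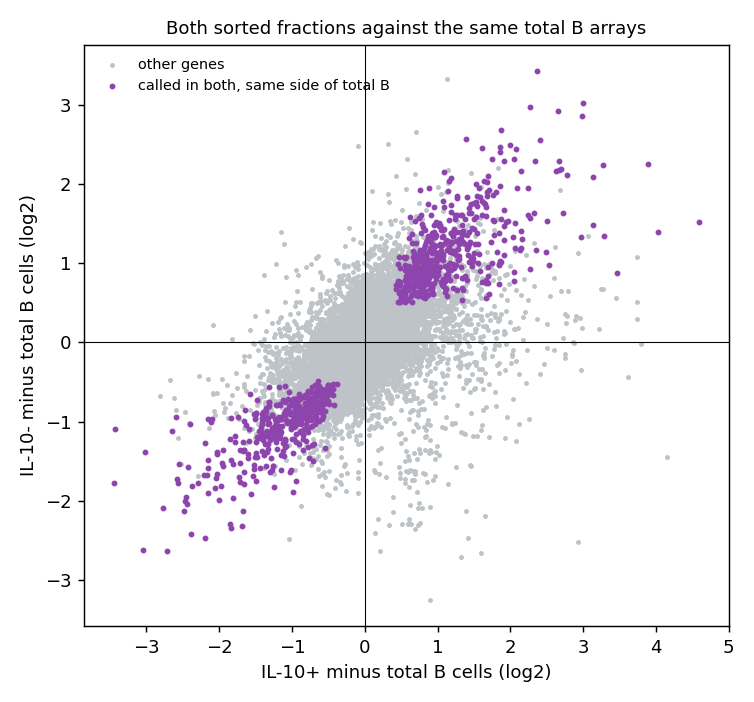
Change from total B cells in log2 for IL-10+ cells (horizontal axis) and IL-10- cells (vertical axis), each point a gene, both against the same 2 total B arrays. Purple points are the 884 genes past the threshold on the same side in both comparisons, and grey points are the other genes.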

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

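The tests of B-1 cells, of all variable genes within each slide, of a mixture and of T cells were chosen after the result was seen. Among 167 values checked over the 5 IL-10+ arrays, 11 had an array far from the others, against 8.3 that chance gives. The gap as a share of the range was 0.727 for Cd80 and 0.721 for Cdc6, from replicate 2. It was 0.72 for Cgas and 0.782 for Hbb-b1, also from replicate 2. For replicate 1 it was 0.805 for Cflar and 0.794 for Cox6a1. For replicate 5 it was 0.734 for Hspa1a, 0.718 for Hspa1b, 0.771 for Itgb7, 0.765 for Pfkp and 0.717 for Tlr1.

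Immunoglobulin variable genes made up 6 of the named largest rises in IL-10+ cells. All 6 were higher by over 2 standard errors within each slide, which their choice as genes without overlap between the groups largely fixed. Of all 56 measured variable genes, 30.4% rose in a fit of slide 1 alone, against 4.1% of all genes. That argues against the slide as the whole cause. The 56 were not picked by their change, but a gene detected only on IL-10+ arrays, such as Ighv7-3 among the fractions, could pass the filter. This tilts the set towards rises, although all genes passed the same filter. None of the 56 measured variable genes, 0%, lay below 0, and 46 rose, with a median of 2.29 log2. A rise of all immunoglobulin RNA would give this, but so would any cause that raises variable genes, so it does not separate them. The 6 measured genes of the immunoglobulin list had a smaller median, 1.53 log2, and the constant gene Igkc among them changed by 0.81 log2. Iglv1 is in both sets, and brightness differed. On IL-10- arrays Ighm lay at 14.182 to 14.393 log2 and IGH-V11 at 4.941 to 6.263. The 2 medians are therefore not a like comparison. Probes of related variable genes may read the same transcripts, which was not checked, so the 56 may not be separate measurements. More B-1 cells in the fraction is a candidate explanation too, since 71.4% of the measured B-1 list genes rose. Of 13 plasmablast and plasma cell genes 9 rose as well, so a high share was not particular to B-1 genes. These explanations stay open together, as does a difference tied to IL-10 secretion itself, which was not tested.

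Total B cells lay outside the range of the sorted fractions for 884 genes, 496 higher and 388 lower in both fractions, against 25 on opposite sides. A mixture of the 2 fractions would place total B cells between them. In 100 simulations of unchanged groups against shared total B arrays, at most 1 such gene arose. No group differed in them, so hardly any gene could pass. They therefore do not show how many such genes a mixture, or shared arrays with groups that differ, would give. Independent lists of these sizes would share 101 higher and 70.2 lower genes, and part of the excess may come from the shared arrays. Within slide 2, 100% of the 884 genes had the same directions and 595 genes passed on the same side in both comparisons there, though these arrays had also helped to select the genes. Staining and sorting, confounded with the groups, cannot be told apart from a difference between the cells, with 4 of 24 immediate early genes higher and 2 lower in both fractions. Of 4 measured erythroid and platelet markers, not tested as a list, 3 were lower in IL-10+ and 2 in IL-10- cells than in total B cells, with 0 higher.

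T cell genes higher in IL-10+ cells could come from T cells in the gate, which the B cell isolation and flow sorting named in the labels should remove. Of the 19 T cell marker genes on the array, 6 were detected on most IL-10+ arrays and 12 on none of them, among these Cd3d, Cd3e, Thy1 and Trac. The brightest of 3 Cd8b1 probes and the Lck probe were detected on all arrays of each group, with changes of -0.03 and 0.52 log2 at adjusted p values of 0.915 and 0.123, while another Cd8b1 probe was detected on 5 of 5 IL-10+ arrays and on none of the others, and the remaining probe on none. Because detected and undetected markers were mixed, T cells and expression in B cells cannot be told apart here. These genes were named after their values were seen.

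Among the 8 splits that part all 3 replicate pairs, the real one gave 2028 genes and the highest other 0, and 8 splits are too few for a share under 0.05. Of all 56 splits of the 8 arrays, most of which leave a pair together, 1 gave as many genes, the real one, and the highest other gave 23. For gene lists 3 of the 56, the real one included, called at least 13 lists and the highest other called 14, so chance cannot be excluded.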

How the results depend on the processing

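The within-pair tests of array measures, the within-slide and median-scaling tests of gene lists, all alternatives for the lists against total B cells, the fit without immunoglobulin genes and the fits without the arrays farthest from their groups were chosen after seeing the data. Il10 stayed past the threshold in each alternative run, and leaving out single arrays gave 5.32 to 5.52 log2. Between IL-10+ and IL-10- cells the count was 1337 with the replicate block, 751 within slide 1 and 617 within slide 2, where fewer arrays were fitted, and 1255 to 2020 with single arrays left out. The lowest came without IL-10- replicate 2. Among the lists and named genes refitted with it, the replicate block changed no other call than those given with the results. Leaving out IL-10+ replicate 1 and IL-10- replicate 5 gave 1747 genes. The authors' processed values gave 1868 of 9679 probes, with no gene named. Against total B cells, median scaling gave 1318 for IL-10+ and 606 for IL-10- cells, the fit of 2 groups 431 for IL-10- cells, and single omissions 1015 to 2390 and 398 to 1551. The replicate block, whose pairing of total B arrays was not checked, gave 1888 for IL-10+ against total B cells. Gene lists numbered 0 with an estimated correlation, 20 with fry and 12 to 14 with single omissions between the fractions. For IL-10+ against total B cells they numbered 1, 13 and 4 to 8, the lowest without total B replicate 2. For IL-10- against total B cells they numbered 0, 8 and 1 to 7, the lowest without IL-10- replicate 2, with 3 without IL-10- replicate 3, 2 without total B replicate 2, 2 under the slide block, 2 without background correction and 1 within slide 2. Of 2624 values of 120 named genes between the fractions, 2349 kept direction and side of the threshold, 264 lost the threshold, 3 gained it and 8 turned. Median scaling turned Cad to 0.036, Cox6a1 to 0.248, Hdc to 0.474, Ppan to 0.073, Rplp2 to 0.037 and Rps18 to 0.069, each below the median of all genes, 0.48. Hdc was 0.013 with the block and -0.065 to 0.025 with single arrays left out. The cause of the other changes was not tested. Signal over background limits genes undetected in a group to bounds. Il10 and the lists could not be computed from the authors' values, whose identifiers were not paired.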

Other observations

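The neighbours of Il10 that passed lay on the same side of the gene; no test compared the sides. Il19 and Pigr, at 1 and 5 places on that side, rose. Il24, at 3 places, passed as higher, but its fold was 0.879 with the IL-10- arrays raised to the lowest detected signal. Fcmr and Yod1, at 4 and 8 places, had changes of 0.17 and 0.22 log2 at adjusted p values of 0.352 and 0.302. On the other side, Mapkapk2 had a change of 0.34 ± 0.11 log2 (SE) at an adjusted p of 0.0507, and Dyrk3, Eif2d, Rassf5, Ikbke and Srgap2 had adjusted p values between 0.397 and 0.962. Apart from Il19, Il24 and Pigr, these neighbours were chosen for naming after their values were seen.

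IGH-V11 changed by 5.59 log2, against a median of 2.29 over the 56 measured variable genes. IGHV12S1 changed by 2.83 and was chosen for naming after its value was seen. The kappa constant gene Igkc changed by 0.81 ± 0.14 log2 (SE), named on the same basis. RN18S was 1.43 ± 0.39 log2 (SE) higher in IL-10+ than in IL-10- cells, with an SD of 1.15 among the 3 IL-10- arrays, and was named for this comparison after its value was seen. In omissions of single arrays, chosen after seeing the data, its change was 0.78 log2 without IL-10- replicate 5, and its adjusted p of 0.03 became 0.0541, 0.0628 and 0.0603 without IL-10+ replicates 2, 4 and 5.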
